A study of Nothobranchius furzeri with 10 samples.

How the data were processed

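RNA was sequenced from the livers of male Nothobranchius furzeri of the inbred strain GRZ, a short-lived annual killifish, at 10 weeks of age. Libraries were made from total RNA with the TruSeq RNA kit, per the labels' protocols. All 10 samples carry the label of swim-tunnel exercise, in which a fish swims against a water current, and no other strain, age, sex, tissue or perturbation is labelled. They therefore formed 1 group of 10 libraries, and a comparison of exercised with resting fish was not analysed here. The libraries are called 1 to 10 in the order of their records, and the number serves only as a name. The labels do not say whether each library came from a different fish, so the spread between these samples may in part be technical. The p-values compare these samples with the reference named for each test and do not separate technical from biological spread.

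The authors deposited a table of whole-number read counts per gene for 26739 genes. Reads were demultiplexed with bcl2fastq 1.8.4, aligned with STAR 2.4.1d and counted with featureCounts 1.4.6-p4, per the submitters' processing notes. The genome build, annotation and counting options are not given in the sources used here, so reads shared between near-identical or overlapping genes may be split or lost in an unknown way. The authors also deposited RPKM values (counted reads scaled by gene length in kilobases and by library total) for the same genes and libraries. The gene length implied by each pair of count and RPKM was computed with the library's own total and with the totals of all libraries taken in rotation down the rows, as happens when a short vector is recycled along a table. The rotating totals gave 1 length per gene. Deposited RPKM values therefore share no scale between libraries or between genes of 1 library. They were used only for the implied lengths, to describe the scaling error and for the planned shares of RPKM. RPKM values were recomputed from the counts, the implied lengths and each library's own total.

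Gene identifiers of the form Nfu_g_1 are not paired with gene names in the tables, and 0 of 26739 matched the 38438 genes of the reference table (assembly NfurGRZ-RIMD1). Genes were therefore left unnamed. The 35 gene lists, 16 isozyme pairs and 20 pairs of lists fixed before the data were examined could not be matched, and the 3 analyses planned on them were not run. The rule fixed for the genes to be named (the most abundant and most variable genes that have a symbol, and leading list members) named no gene. The 4 identifiers printed in the results were chosen after their values were seen.

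Genes with at least 1 CPM (counts scaled to a common library total of 1000000) in at least 5 libraries were tested, which left 14013 genes holding 99.8% of all counts. Library sizes were scaled by trimmed means of M values in edgeR 4.0.16, and log2 CPM values used a prior count of 2. Variation beyond counting noise was tested per gene with a Pearson chi-square test of the counts against a Poisson model with 9 degrees of freedom. Variation beyond that of genes of like abundance was tested from edgeR's quasi-likelihood fit (intercept only, trended dispersion, robust prior), with the residual quasi-dispersion over its trend referred to an F distribution. Both p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The spread is given as the biological coefficient of variation (BCV), the square root of edgeR's tagwise dispersion. That dispersion is moderated towards the abundance trend, so a gene with no spread beyond counting noise still has a BCV well above 0.

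Genes that varied together were found by average-linkage clustering on Pearson correlation over the libraries, among genes with an SD of log2 CPM above 1.5. The tree was divided at a height of 0.3 and groups of at least 10 genes were kept. This grouping was chosen after the data were seen. For comparison, each gene's values were permuted over the libraries 100 times, which gives the level for genes that vary independently. Relations with library depth were tested as Pearson and Spearman correlations with 100000 two-sided permutations and Benjamini-Hochberg adjustment over 8 relations.

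The steps were tested on simulated data with the means and library sizes of the 14013 tested genes. The counting-noise test recovered 97.0% of 200 genes given extra variation and called 0.0796% of the others. The F test recovered 99.5% of 200 genes given a raised dispersion when all other genes shared 1 dispersion, which is a simpler setting than these libraries. The grouping recovered all of 100 genes given 1 strong common profile among genes that varied independently, which is a simpler setting than the groups found here. R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were also used.

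Depth ranged from 13806555 to 39405713 counted reads per library. A count of 3, the upper limit that a count of 0 allows, corresponded to 0.0761 to 0.217 CPM. Binomial intervals are exact 95% Clopper-Pearson intervals, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Alternatives covered the size factors, the filter on low counts, thinning to the smallest total, the reference distribution, DESeq2's dispersion outliers, shares of RPKM, the settings of the grouping and leaving out each library.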

Results

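Liver transcriptomes were measured by RNA sequencing in 10 libraries from male GRZ killifish, all labelled as exercised in a swim tunnel. The libraries held 29927669 ± 8582533 counted reads (SD, n = 10), from 13806555 in library 2 to 39405713 in library 7. Reads were found for 19999 ± 321 of 26739 genes per library (SD, n = 10), and 4591 genes had no read in any library. Because the labels give 1 condition, the data address which transcripts made up the liver RNA of these fish and how far the libraries differed from each other. Genes are given by identifier, since the tables do not pair identifiers with names.

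Liver RNA was dominated by few transcripts. The most abundant gene of a library took 4.04 ± 1.21% of its counts (SD, n = 10), the 10 most abundant took 19.9 ± 1.75% and the 100 most abundant took 46.9 ± 2.57%. These shares depend on the unit: as shares of summed RPKM recomputed from the counts they were 7.19%, 22.5% and 55.8%. Between 89 and 156 genes made up 50% of the counts of a library. Nfu_g_1_014314 led in 6 libraries and Nfu_g_1_015843 in the other 4. Nfu_g_1_014314 was steady, with 3.58 ± 0.406% of counts (SD, n = 10) and a 1.33-fold difference between the highest and the lowest library. Nfu_g_1_015843 took 3.49 ± 1.48% (SD, n = 10) and was highest in library 1, at 7.33% (exact 95% interval 7.32 to 7.34%). Without library 1 the mean share of the leading gene was 3.67%.

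The 20 genes with the largest mean share together held 25.3% of the counts, and only 4 genes were among the 10 most abundant in every library. Of these 20 genes, 4 differed by less than 2-fold between the highest and the lowest library. Another 6 differed by 11.3-fold to 13.8-fold, and all 6 were lowest in library 3. Without library 3 the differences were 2.86-fold to 3.36-fold. The shares of these 6 genes moved together, with a lowest pairwise correlation of log2 share of 0.979 across libraries and of 0.955 without library 3. They summed to 0.552% of counts in library 3 and to 6.87% in library 4, against a mean of 4.15 ± 2.05% (SD, n = 10).

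Expression differed between libraries by a median SD of 0.42 log2 CPM per gene. The median BCV was 0.331, and the 5th and 95th percentiles were 0.228 and 0.792. These BCVs are moderated towards the abundance trend, so the percentiles are not those of the genes' own spread. In 4 equal classes of genes by rising abundance the median BCV was 0.424, 0.340, 0.293 and 0.295, so it fell over the lower 3 classes and not further in the most abundant. The ratio of the highest to the lowest library was below 2-fold for 30.3% of genes and above 4-fold for 25.4%. A total of 36 genes ranged over more than 10 log2 units of CPM, with a prior count of 2. Of 14013 tested genes, 13826 (98.7%) passed the Poisson test of counting noise at an adjusted p of 0.05. The outcome depends on the count as well as on the spread, and the 187 genes that did not pass had a median mean count of 63.8, against 344.5 for all tested genes.

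No gene passed edgeR's F test for more variation than other genes of like abundance (smallest Benjamini-Hochberg adjusted p = 0.856). At an unadjusted p under 0.05 the count was 730. The prior, with 2.70 degrees of freedom, was estimated from the same ratios, so a share near 5% follows from the fit, and the absence of calls does not show that no gene was more variable than others. When the ratio to the trend was referred to a chi-square distribution, which assumes 1 dispersion per abundance, 3967 genes passed, and DESeq2 marked 231 genes as dispersion outliers, all of them among the 3967.

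Pearson correlations of log2 CPM between pairs of libraries had a median of 0.907 over 45 pairs, from 0.812 to 0.972. No pair of libraries was close enough to be repeat deposits of 1 library: chi-square per degree of freedom was at least 52.3 between any pair. The first component of a principal component analysis held 30.3% of the variance and separated library 3 at one end from libraries 8 and 9 at the other. The second held 26.3% and separated library 1 from library 10. The third held 15.7%. The highest shares in 100 permutations were 13.04%, 12.58% and 12.06% for these components. The 4th component, at 9.43%, did not exceed its permuted value. Shares add up to a fixed total, so large early components leave less for later ones. The 4th share therefore does not show that shared variation ended at the third component.

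**Figure D1:**
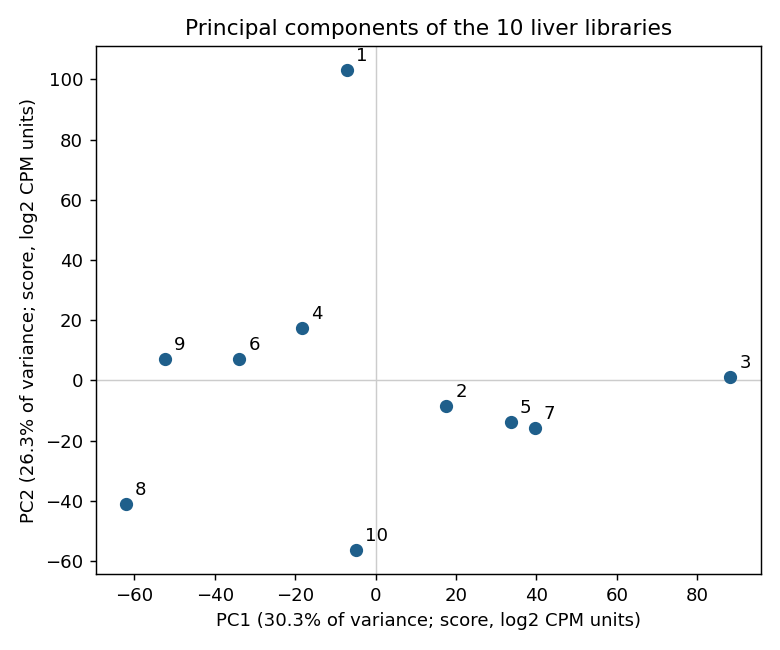
Scores of the 10 libraries, marked by library number, on the first and second principal components of log2 CPM over 14013 genes, in log2 CPM units. Library 3 lies far to the right at 88.2 on the first component and library 1 far up at 103 on the second.

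The most variable genes fell into groups that rose and fell together. Of 485 genes with an SD of log2 CPM above 1.5, 413 fell into 6 groups of at least 10 genes. No such group formed in 100 permutations of each gene alone, which shows only that the genes did not vary independently. These numbers depend on the settings: 1152 genes fell into 22 groups with an SD above 1 and 186 into 4 groups with an SD above 2, and complete linkage gave 10 groups. Group 1 held 190 genes and was highest in library 1, with a median of 5.06 log2 CPM, against -0.76 in library 8. It took 3.07% of the counts of library 1 and at most 0.441% of any other library. Without its leading member the share of library 1 was 1.34%, and at most 0.436% elsewhere. Its leading member, Nfu_g_1_001220, reached 14.26 log2 CPM in library 1, while the next highest library had 5.71 and the lowest -0.14. Group 1 was also above its lowest levels in libraries 7, 3 and 9, with medians of 3.19, 2.80 and 2.61 log2 CPM. Its membership leaned on single libraries: 55 members were shared with the best matching group without library 1, 120 without library 8 and 125 without library 7.

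Group 2 held 161 genes and differed more widely. Its median was 5.81 log2 CPM in library 3 and 5.09 in library 7, then 3.54 in library 5, 2.76 in library 10 and 2.21 in library 2. It lay at 0.11 in library 6 and between -1.74 and -0.68 in libraries 1, 4, 8 and 9. The group took 4.96% of the counts of library 3 and 3.49% of library 7, but 0.0216 to 0.0264% in libraries 1, 4, 8 and 9. Its share was 1.03 ± 1.74% (SD, n = 10), a mean carried by libraries 3 and 7, since no other library exceeded 0.794%. The best matching group shared 87 members without library 3, 95 without library 7 and 105 or 106 without library 10, 2 or 5.

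Group 3 held 22 genes, and its medians fell into separate ranges. They lay between 4.35 and 6.26 log2 CPM in libraries 1 to 5 and between 1.79 and 2.35 in libraries 6 to 10. Its leading member, Nfu_g_1_008031, was at 10.598 to 10.999 log2 CPM in libraries 1 to 5 and at 5.127 to 7.140 in libraries 6 to 10. Group 4, of 15 genes, had medians from -1.89 to -1.32 log2 CPM in libraries 3, 8 and 9 and from 1.65 to 4.06 in the others. Group 5, of 13 genes, was lowest in library 8, at -1.42, and highest in library 5, at 4.98. Group 6, of 12 genes, was highest in libraries 1 and 6, with medians of 5.42 and 4.48 log2 CPM, and at most 2.53 in the others. Of group 3, 10, 13 or 14 members stayed together without libraries 1, 4 or 5. Group 5 had no matching group without library 5 or 8, and group 6 shared at most 7 members without libraries 1, 2, 6, 9 or 10. Under complete linkage group 5 had no match and group 6 shared 4 members. Group 6 also had no match at a cut height of 0.2 and shared 1 member after thinning, and neither group had a match with an SD above 2.

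**Figure D2:**
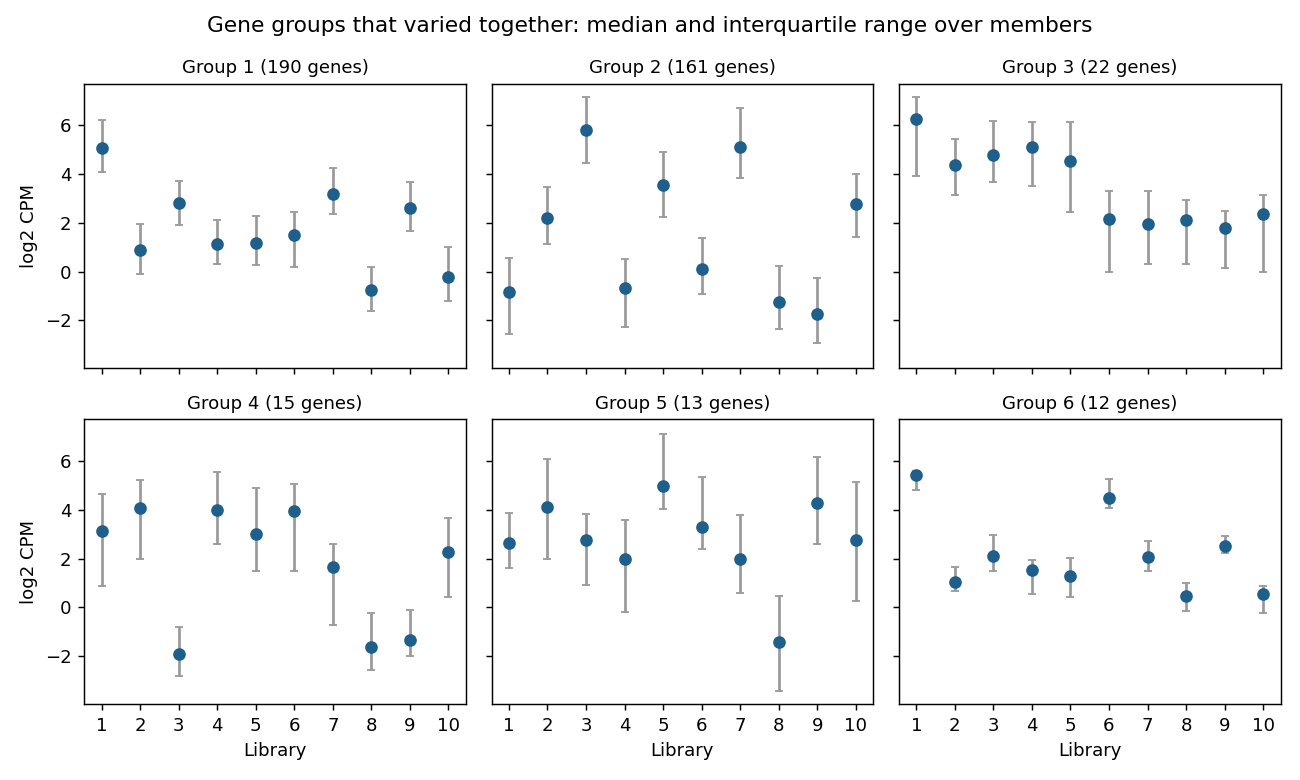
Median log2 CPM (points) and interquartile range over members (bars) of each of the 6 gene groups in libraries 1 to 10. Group 2 spans from -1.74 in library 9 to 5.81 in library 3, and group 3 lies above 4.3 in libraries 1 to 5 and below 2.4 in libraries 6 to 10.

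No relation with sequencing depth passed the test after adjustment. The number of detected genes had a Pearson r of 0.685 with log2 total counts (permutation p = 0.0294, adjusted p = 0.235, n = 10) and a Spearman rho of 0.685 (permutation p = 0.0351, adjusted p = 0.281). Without libraries 2 and 10, the farthest from the median depth, r was 0.334. For the share of the 10 most abundant genes, components 1 and 2 and the medians of groups 1, 2, 5 and 6, Pearson r lay between -0.398 and 0.285, with adjusted permutation p of at least 0.740. Spearman rho lay between -0.503 (group 5, adjusted p = 0.575) and 0.176. Without libraries 2 and 10, r reversed its sign for all of these measures but group 5, with values from -0.415 to 0.243, and went from -0.398 to -0.574 for group 5. These values were not tested. No pooled correlation was computed for groups 3 and 4, whose medians fell into separate ranges. The medians of groups 2 and 5 also left wide gaps but were pooled. Group 2 went from 0.11 in library 6 to 2.21 in library 2, and group 5 from -1.42 in library 8 to 1.97 in library 4. The values of group 5 may rest on library 8, which held 39170190 counted reads, and they were not computed without it.

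The numbers in the sample titles run in the order of the libraries and skip 1 number between libraries 5 and 6. The labels do not say what these numbers stand for. In 2268 of the 14013 genes, the values of libraries 1 to 5 and of libraries 6 to 10 did not overlap. There are 126 ways to split the libraries into 5 and 5, and since a gene can be parted by only 1 of them, the average over splits is at most 111 genes. The highest count of any other split was 546. Libraries 1 to 5 were higher in 925 of the parted genes and lower in 1343. The gap between the ranges was above 1 log2 unit in 49 genes, and in 39 of these libraries 1 to 5 were higher. Of the 22 genes of group 3, 18 were parted, and of groups 1 and 2, 0 were. These counts follow largely from the profiles by which the groups were formed, so they add no support for the parting. Depth overlapped, from 13806555 to 35599186 counted reads in libraries 1 to 5 and from 16888685 to 39405713 in libraries 6 to 10. The median correlation of log2 CPM between libraries was 0.907 among libraries 1 to 5, 0.917 among libraries 6 to 10 and 0.903 across the parts, and no correlation with depth was computed within a part, since a minimum of 6 libraries was set.

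**Figure D3:**
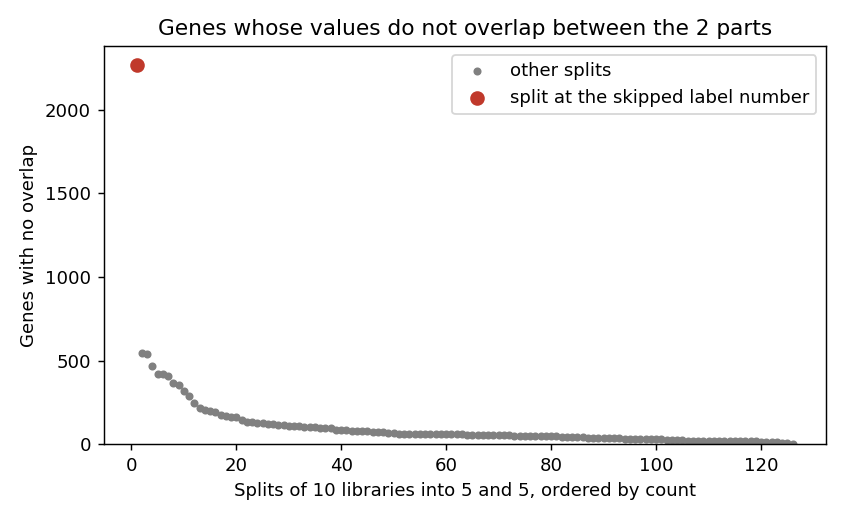
Number of genes whose log2 CPM values do not overlap between the parts, for each of the 126 splits of the libraries into 5 and 5, ordered by count. The split at the skipped label number parts 2268 genes, and the next highest parts 546.

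The deposited RPKM table did not follow from the counts and each library's own total. For 3039 genes with all values above 5 RPKM, the gene length implied by count and RPKM varied between libraries with a median coefficient of variation of 52.0% when each library's own total was used. It varied by 0.00122% when the totals were taken in rotation down the rows. Rotation rebuilt 99.987% of the 199993 values above 0 within 0.001 RPKM plus a relative 0.001, against 11.6% with own totals. Both rebuilds used lengths fitted to these values under rotation, and for 10.0% of the values the rotation gives the own total. The 11.6% is therefore not a separate test of own totals. The deposited values were between 0.350 and 2.85 times the recomputed ones, and 31.7% were off by more than 1.5-fold. The library with the highest value differed between the deposited and the recomputed table in 2153 of the 3039 genes (70.8%). The median SD of log2 RPKM over libraries was 0.80 as deposited and 0.38 when recomputed.

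**Figure D4:**
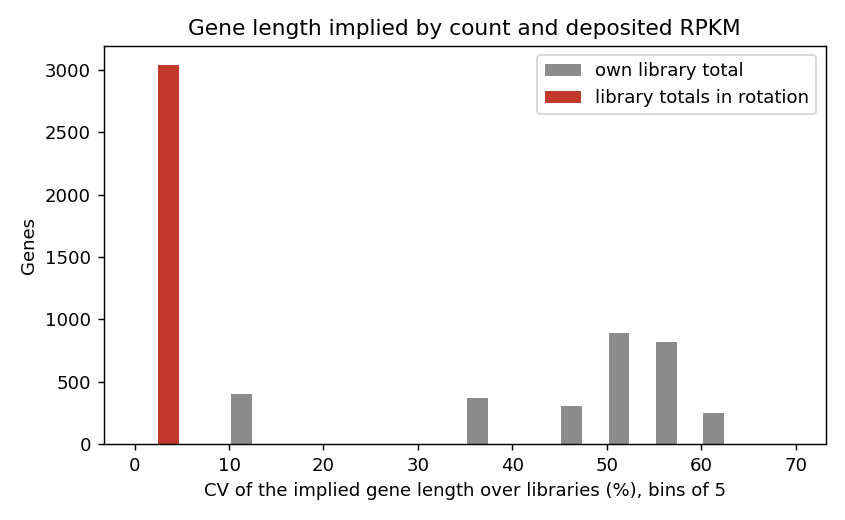
Number of genes by the coefficient of variation over libraries of the gene length implied by count and deposited RPKM, in bins of 5%, for division by the library's own total (grey) and by totals in rotation (red). All 3039 genes fall in the lowest bin with totals in rotation, and none do with own totals.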

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

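Of 17 per-library values tested for a single library far from the rest, 4 were marked. The criterion marks about 1 in 20 by chance if values are normally distributed over libraries, which was not checked. The tally is inflated, since 1 value counts under 2 names and Nfu_g_1_001220 was tested because it leads a gene group that is highest in library 1. The most abundant gene of library 1, Nfu_g_1_015843, took 7.33% of its counts, so that the same 7.33% appears for the leading gene and for this gene. In library 1, Nfu_g_1_001220 was at 14.26 log2 CPM. In library 8, the median of gene group 5 was low, at -1.42 log2 CPM. Across single genes, the same criterion marked 1135 of 14013 genes, against 701 by chance if values were normally distributed. The excess may therefore reflect the shape of the values. Library 1 was the extreme one in 515 genes, library 6 in 275, library 3 in 147 and library 10 in 111.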

How the results depend on the processing

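The alternatives were fixed before the data were examined, except those on the gene groups, the parted genes, the recomputed RPKM and the separate parts of 5 libraries. Shares of the leading, 10 leading and 100 leading genes moved by more than 1 SD when RPKM replaced counts. They were 7.21%, 23.3% and 56.8% as deposited and 7.19%, 22.5% and 55.8% recomputed. Within a library the recomputed RPKM differs from the counts only by gene length, so the weighting by length moved these shares. As deposited, genes of 1 library were divided by different totals, so those values are not true shares. Leaving out the most abundant gene moved the share of the next 10 to 17.5%. Leaving out 1 library gave 3.67 to 4.13%, 19.6 to 20.3% and 46.4 to 47.3%. The count of genes beyond counting noise stayed within 1.5 times of 13826 under each alternative. It ran from 9879 with at least 5 CPM (fewer genes tested) to 17986 with no filter (more genes tested), and from 13528 to 13704 with 1 library left out. Among libraries 1 to 5 and 6 to 10 alone it was 12569 and 12465 of 14013 genes, and the F test called 0 in each. The F test called 0 genes under median-ratio size factors, each filter, thinning, a non-robust prior and each left-out library, against 3967 with the chi-square reference (which by construction assumes 1 dispersion per abundance) and 231 in DESeq2 (the cause was not tested). Genes in groups numbered 1152 with an SD above 1 and 186 with an SD above 2, since the minimum sets how many genes enter. Under 6 other settings they ranged from 363 to 426, and with 1 library left out from 289 to 432. With 1 library left out, at least 55, 87, 10 and 10 members of groups 1 to 4 were shared with the best matching group, with library 1, 3, 1 and 2 left out. Over the 8 other settings the fewest shared members of groups 1 and 2 were 41 (SD above 2) and 71 (complete linkage), and groups 4 to 6 had no match with an SD above 2. Group 5 also had none under complete linkage. Group 6 also had none at a cut height of 0.2, shared 1 member after thinning and 4 under complete linkage or Spearman correlation, and merged into a group of 205 genes at a cut height of 0.4. The parted genes numbered 2288, 2147 and 1873 with median-ratio size factors, thinning and at least 5 CPM. The 3 planned analyses of gene lists and isozymes gave no value, since no identifier could be named. No paired analysis was possible because the labels give 1 group. Depth limits the weakest genes: in library 2 a count of 3 is 0.217 CPM.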

Other observations

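Tests of the group 2 slope, of the splits and of the RPKM scaling were chosen after the result was seen, and the tests of thinning and of gene length before. The design names no second group, so no explanation by treatment was tested.

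Genes next to each other in the table varied together more than random pairs. Over 8520 adjacent pairs of tested rows the median correlation across libraries was 0.11, against at most 0.02 in 100 draws of random pairs, and 7.85% of adjacent pairs had a correlation above 0.8, against 2.30% of random pairs. Whether the rows follow genome order is not given in the sources used here.

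Gene group 2 differed about 188-fold between the medians of library 3 and library 9. The size of this fold depends in part on the prior count of 2, since the median in library 9 was -1.74 log2 CPM. After every library was thinned to the smallest total, the median SD of its members was 2.62 log2 units. Unequal counting depth alone therefore does not account for the difference. Thinning does not remove an effect that travels with depth. The group median had a Pearson r of -0.095 with log2 total counts (adjusted permutation p = 0.852, n = 10). Gene length alone does not set the members apart: 1544 genes of matched length outside the groups had a median deviation of 0.00068 log2 units in library 3. The median of the members was 4.55. The members were of usual length (median 2791 bp, against 2885 bp for all tested genes), so the scaling alone would put matched genes near 0. A bias that acts on length together with another trait was not tested. A candidate explanation is RNA of another tissue or cell population taken up in varying amount, which would keep the members at 1 ratio to each other: 55.4% of the 92 abundant members had a slope between 0.8 and 1.2 on the group median over the 6 higher libraries, which lies between the 80% set for that explanation and the 50% set against it. The median of these slopes was 1.14, since the abundant members were set against the median of all 161 members. A fixed ratio asks for slopes equal to each other and not for slopes of 1. The window was therefore off centre, and the share may understate how constant the ratio was. The candidate explanation cannot be told apart from joint regulation. The share fell between the limits, and the genes have no names to identify a source. Group 1 gave 59.09%, with a median slope of 0.979, but its slopes spread more widely. Their 5th and 95th percentiles were 0.549 and 1.72, against 0.679 and 1.31 in group 2. The cause of group 1 is also unknown, so it is no reference for joint regulation.

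The labels give 1 set of characteristics for all 10 libraries, yet 2268 genes parted libraries 1 to 5 from libraries 6 to 10. Of the 126 splits into 5 and 5, 1 parted as many genes, the one at the skipped number, and the highest other parted 546. The split is set by the titles, but it was taken up because the values pointed to it, and the genes are correlated, so the count restates the pattern and does not settle whether chance can be excluded. Unequal counting depth alone does not account for the parting, since 2147 genes were parted after thinning. Thinning does not remove an effect that travels with depth, but the depths of the parts overlapped. A condition, tank, harvest or sequencing batch that differs between the libraries may lie behind the parting and stays open, since the labels hold 1 set of characteristics and cannot tell these apart. The parting is not evidence for a treatment effect, and what the number skipped in the sample titles separates would need to be learned from the submitters.

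The deposited RPKM values are consistent with division by library totals that were recycled down the rows of the table: the implied gene length then varied by 0.00122% between libraries. A different factor per library, such as an effective library size, could not produce them, since the implied length still varied by 28.4% after each library's median ratio was removed. Single values were off by up to 2.85-fold, and a comparison of 1 gene between 2 libraries based on the deposited RPKM would carry an error of up to 8.15-fold. Genes within 1 library were also divided by different totals, so their deposited values are not on 1 scale either. The counts are unaffected.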
